A study of Mus musculus with 6 samples.

How the data were processed

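Gene expression was measured by RNA sequencing of bone marrow LSK cells in 3 wild-type and 3 HDAC6 knockout samples. RNA was extracted with Trizol and libraries followed standard Illumina protocols, per the labels' protocols. The submitters' processing notes name HISAT2 2.2.1, SAMtools 1.13, featureCounts 2.0.3, DESeq2 and the build GRCm39, without saying which tool made which values. The annotation, the strand setting and the treatment of reads shared between genes are not given in the sources used here.

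The deposited table held 16022 gene symbols, with an estimated count and an FPKM value per library, per the file headers. Between 19.6% and 20.9% of the deposited estimated counts per library were not whole numbers, so they were rounded before testing. The deposited FPKM values served only for 1 alternative. Symbols were used as the table gives them, and 15392 of the 16022 were found in the GENCODE M21 annotation of GRCm38. Since this build differs from GRCm39, it served for names, chromosome membership, gene order and transcript length and GC content, and no coordinates are given. Total counts ran from 25993971 to 28743672 per library, and 3 counts, the limit that a count of 0 allows, corresponded to 0.106 to 0.114 CPM. Such limits cover counting error only. To find a library deposited more than once, library pairs were compared with sampling noise. Chi-square over degrees of freedom was 35.1 to 58.4 within groups and 25.8 to 91.4 between them, the lowest being WT replicate 3 with knockout replicate 3, so each library counted as 1 sample. This does not show that the samples came from separate animals.

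The comparison, its test, the named-gene rule, the gene lists and most alternatives were fixed before the data were examined. Knockout was compared with WT by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust dispersion, glmQLFTest), after filterByExpr with its default minimum count of 10 and TMM normalization. The filter left 12875 genes, TMM factors ran from 0.952 to 1.034, and the threshold was a Benjamini-Hochberg adjusted p of 0.05 with no fold minimum. This fit was first run with the newer quasi-likelihood option of edgeR (legacy off), and was then set to the default that the plan named after both results had been seen. The newer option is therefore given as an alternative. DESeq2 was likewise first run with its independent filtering set for the 0.05 threshold, and then with the default named beforehand. Standard errors are the log2 fold change divided by the root of the F statistic. Levels are TMM-normalised CPM, as mean ± SD of 3 libraries.

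Named genes were Hdac6 and Idh1, then the 8 per direction with the smallest p among genes with non-overlapping groups and a mean of at least 5 CPM in 1 group (the rule for fewer than 5 passing genes), and the 4 members with the smallest p of each list described. Other genes named in the text were chosen after their values were seen. One item that the rule selects is not reported here. Of 39 fixed gene lists, 37 had at least 5 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Sex-linked transcripts and the mitochondrial genome list were not tested.

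The alternatives chosen beforehand were RLE and upper-quartile normalization, no filter and a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0 with its default filtering, limma-voom with sample weights, non-robust dispersion, the replicate number as a block, each library left out, an adjusted p of 0.01, a log2 fold change of at least 1, and for lists an estimated correlation and the directional test of fry. Added after the data were seen were limma on log2(FPKM + 1), DESeq2 on the filtered genes and with filtering set for 0.05, the newer edgeR option, library size alone for lists, the fry test for change in either direction, and the deacetylase list without Hdac6.

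The tests were checked on simulated counts for the 12875 genes of this comparison, in 5 simulations with 200 changed genes each. At 1.5-fold, 2-fold and 4-fold changes edgeR recovered 28.1%, 78.5% and 97% of changed genes, with 8.6% of its calls false, and DESeq2 recovered 43.9%, 86.9% and 98.8%, with 20.2% false. A list of 30 genes shifted 1.3-fold was found in 5 of 5 simulations with the preset and with the estimated correlation, with 0 false lists. The simulated genes varied independently of each other.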

Results

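RNA was sequenced from mouse bone marrow LSK cells, the lineage-negative, Sca-1-high and c-kit-positive fraction that holds hematopoietic stem cells and early progenitors. The 6 libraries fell into 2 groups of 3, wild-type (WT) mice and mice deficient in HDAC6, a mainly cytoplasmic deacetylase whose known substrates include tubulin and HSP90. Total counts per library ran from 25993971 to 28743672. The series addresses how HDAC6 and the metabolic enzyme IDH1 bear on these cells, and the design holds a single comparison, knockout against WT. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples.

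Hdac6 mRNA fell 6.31-fold in the knockout and was the only gene past the threshold by edgeR. As groups, genes of cholesterol synthesis, stem cell identity and neutrophil granules were lower in the knockout. The leading neutrophil genes were at low levels, and whether mature cells left in the sort contributed to them was not tested. Genes of the cell cycle, the unfolded protein response and chaperones were higher, as was a list of mature T and natural killer cell markers. Within that list the T cell genes Cd3e, Cd3d and Cd3g exceeded the WT mean by at most 0.47 CPM. The list mean of knockout replicate 1 lay within the WT range. In knockout replicate 3 the means of the stem cell, G1/S, unfolded protein and heat shock lists lay within the range of the WT libraries. Apart from Hdac6, 0 single genes of these groups passed the test over all genes. Every group call was lost when the correlation between genes was estimated from the data. With the preset correlation 15 lists passed for the real groups, and up to 19 for splits of the libraries that mixed the genotypes. The small p-values of the lists therefore do not by themselves show an effect of genotype.

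Hdac6, an X-linked gene, stood at 60.2 ± 7.03 CPM (SD, n = 3) in WT and 9.53 ± 1.80 CPM (SD, n = 3) in the knockout, 15.8% of the WT mean. Its log2 fold change was -2.66 (SE 0.19), with an adjusted p of 0.000594 by edgeR. Each knockout library (7.69 to 11.28 CPM) lay below each WT library (54.32 to 67.97 CPM), and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. The labels do not say which part of the gene was deleted, so the remaining counts can come from any part of it. Idh1, which encodes cytosolic isocitrate dehydrogenase, measured 61.0 ± 3.78 CPM in WT and 77.5 ± 31.1 CPM in the knockout (SD, n = 3 each), a log2 fold change of 0.35 (SE 0.23) with an edgeR adjusted p of 0.522. Knockout replicate 2 alone stood at 113.36 CPM, and without it the log2 fold change of Idh1 was -0.03.

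**Figure D1:**
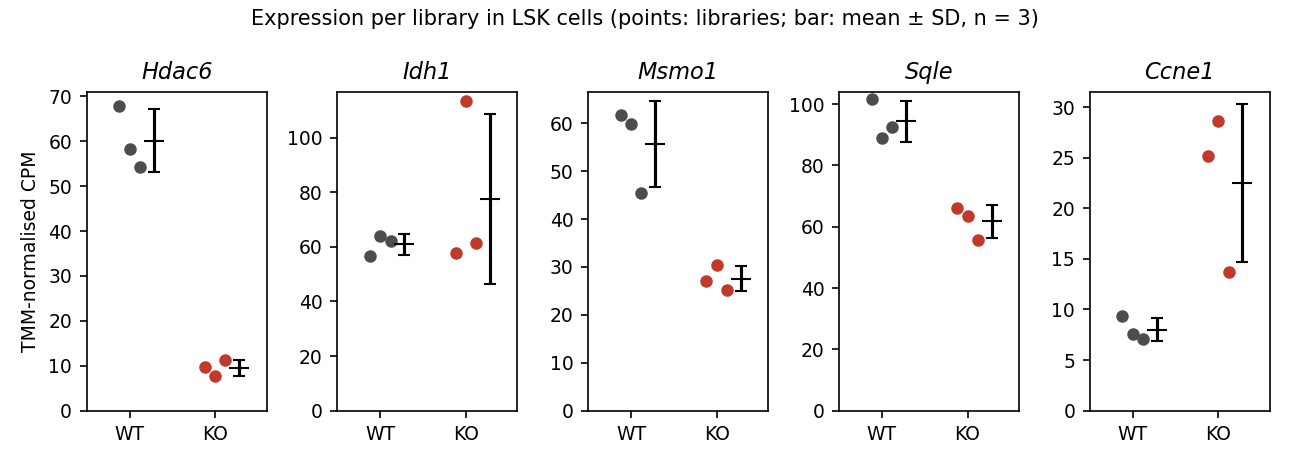
Expression of 5 genes per library in TMM-normalised CPM (vertical axes, starting at 0) for wild-type (WT, grey) and HDAC6 knockout (KO, red) LSK cells. Points are libraries and bars the mean ± SD (n = 3). Hdac6 lies between 7.69 and 11.28 CPM in the knockout libraries, Idh1 reaches 113.36 CPM in knockout replicate 2, and Msmo1, Sqle and Ccne1 show groups that do not overlap.

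Of 12875 genes tested by edgeR, 0 were called higher and 1 was called lower, the targeted gene itself. At an unadjusted p under 0.05 there were 932 higher and 792 lower genes, against 644 expected by chance in all, and the next lowest adjusted p was 0.15. Setting WT replicates 1 and 2 with knockout replicate 3 against the other libraries gave 1714 genes at that p, against 1724 for the real groups. The remaining splits that mixed the groups gave 139 to 958. The excess therefore does not by itself show an effect of genotype. In 18.6% of tested genes the 3 values of one group all lay above those of the other, where chance gives 10% on average. That share was not computed for splits that mixed the groups, so it does not by itself show an effect of genotype. DESeq2 called 120 genes higher and 61 lower on the same counts. Without knockout replicate 3, edgeR called 30 higher and 14 lower, and 22 of these 44 genes were also among the DESeq2 calls on all libraries. Without knockout replicate 1 it called Car1 higher and Hdac6, Hmga1 and Gm6958 lower. The related gene Hmga1b went the other way, from 136 ± 12.2 CPM in WT to 286 ± 106 CPM in the knockout, and DESeq2 called it higher. How reads shared between such genes were counted is not given, so the level of Hmga1 is uncertain.

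The genes with the smallest p and non-overlapping groups did not pass the edgeR test apart from Hdac6. On the higher side, Serpina3g measured 404 ± 36.6 CPM in WT and 702 ± 66.5 CPM in the knockout, a log2 fold change of 0.80 (SE 0.11, adjusted p = 0.15). Cers6, a ceramide synthase, had a log2 fold change of 1.12 (SE 0.19), Cpt1a, which brings fatty acids into mitochondria, 0.67 (SE 0.12), and Ccne1, which encodes cyclin E1, 1.49 (SE 0.28). C4b (2.06), Gm40892 (1.22), Chaf1a (1.06) and Endod1 (0.96) completed the 8 genes with the smallest p on that side. On the lower side, the immediate early gene Fos stood at 20.6 ± 7.43 CPM in WT and 5.69 ± 1.52 CPM in the knockout, with a log2 fold change of -1.85 (SE 0.32). Syne2 (-0.81), the sterol exporter gene Abcg1 (-0.48), Ltf (-2.82) and the sterol genes Msmo1 and Sqle were among the others. The edgeR adjusted p was 0.298 for all of these except Serpina3g, and DESeq2 called each of them. Serpina3g and C4b have close paralogs, and how reads shared between copies were counted is not given in the sources used here, so their levels are uncertain.

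Genes of cholesterol and fatty acid synthesis were lower as a group, with 26 of 28 tested members below WT, a median log2 fold change of -0.35 and 13 members with non-overlapping groups. Over all genes 0 members passed, and 6 were lower when adjusted over the list alone, among them Msmo1, Sqle, Fdft1, Srebf2 and Idi1. Msmo1, an enzyme of sterol demethylation, measured 55.6 ± 8.93 CPM in WT and 27.6 ± 2.59 CPM in the knockout, and Sqle, squalene epoxidase, 94.4 ± 6.59 and 61.8 ± 5.41 CPM (SD, n = 3 each). Camera gave the list an adjusted p of 6.6e-09, and adjusted p = 0.602 with an estimated correlation (camera p = 0.0299 before adjustment). Adjusting over the lists gave the same 0.602 to lists with an unadjusted camera p of up to 0.309, so this value does not rank them. The list mean lay below all WT libraries in each knockout library.

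Hematopoietic stem cell genes were lower as a group, with 28 of 39 tested members below WT and a median log2 fold change of -0.32. Camera gave an adjusted p of 0.000394, and adjusted p = 0.602 with an estimated correlation. Mecom, a transcription factor of stem cell self-renewal, measured 60.4 ± 11.6 CPM in WT and 36.2 ± 10.8 CPM in the knockout, and Krt18, which encodes keratin 18, 74.2 ± 7.19 and 51.0 ± 9.28 CPM. Both surface markers of the sort gate are in this list and lay on opposite sides: Kit, the c-kit receptor, at 1272 ± 127 CPM in WT and 875 ± 185 CPM in the knockout, and Ly6a, which encodes Sca-1, at 65.1 ± 4.34 and 107 ± 21.4 CPM. Ly6a was the 1 member that passed when adjusted over the list alone, on the higher side. Knockout replicate 3 had a list mean of 0.13 log2 units above the mean of all libraries, higher than WT replicate 3 at -0.02. The median was -0.58 without knockout replicate 3 and -0.16 without knockout replicate 2.

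Cell cycle genes were higher as a group. Of 53 tested G2/M genes 51 lay above WT, with a median log2 fold change of 0.24 and 22 members with non-overlapping groups, but 0 passed when adjusted over the list alone. The camera adjusted p was 4.53e-09, and adjusted p = 0.602 with an estimated correlation. Plk1, a mitotic kinase, measured 103 ± 6.71 CPM in WT and 155 ± 27.2 CPM in the knockout, and Ccna2, which encodes cyclin A2, 150 ± 42.1 and 263 ± 58.4 CPM, while Bub1 (0.53) and Cdc25c (0.67) had positive log2 fold changes as well. Of 47 G1/S and S phase genes 42 lay above WT (median 0.21, camera adjusted p = 9.26e-07, and adjusted p = 0.602 with an estimated correlation). Ccne1 and Chaf1a, a chromatin assembly factor, passed when adjusted over the list alone, and Rrm2 (0.52) and Tk1 (0.41) followed. The G1/S list mean of knockout replicate 3, -0.08, lay below that of WT replicate 3, -0.04. Cell cycle inhibitors and quiescence genes had a median of -0.20 and did not pass (adjusted p = 0.056), with Btg2 at -0.61, but passed without WT replicate 3 (0.0466), without knockout replicate 3 (0.026, median -0.44) and with no filter on low counts (0.0375). Without knockout replicate 1 the medians of the G2/M and G1/S lists were 0.15 and 0.13, and both passed.

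Genes of the unfolded protein and integrated stress response were higher as a group, with 28 of 33 members above WT and a median log2 fold change of 0.38. When adjusted over the list alone, 16 were higher and 1, Ppp1r15a, was lower. Xbp1, a transcription factor of this response, measured 181 ± 29.4 CPM in WT and 273 ± 24.7 CPM in the knockout, and the endoplasmic reticulum chaperone gene Hsp90b1 752 ± 30.2 and 1089 ± 212 CPM. Creld2 and Sdf2l1 had log2 fold changes of 0.92 and 0.81. The camera adjusted p was 1.08e-08, and adjusted p = 0.602 with an estimated correlation. Heat shock and HSP90 chaperone genes were also higher (median 0.24, 21 of 28 above WT, 11 higher when adjusted over the list alone). Their camera adjusted p was 2.6e-05, and adjusted p = 0.602 with an estimated correlation. Hspa4 (1.01), Hsph1 (0.69), Hsp90ab1 (0.40) and Cct2 (0.33) had the smallest p, and the median was 0.37 without WT replicate 3. In knockout replicate 3 the means of the unfolded protein and heat shock lists, -0.10 and -0.27, lay within the range of the WT libraries. Proteasome and autophagy genes had a median of 0.21, with 41 of 47 above WT (camera adjusted p = 1.87e-05, and adjusted p = 0.602 with an estimated correlation) and 0 that passed when adjusted over the list alone. The lysosomal membrane gene Lamp1 (1.42) and the proteasome genes Psmd3 (0.46), Psmd13 (0.42) and Psmd14 (0.33) led this list, whose median was 0.12 without knockout replicate 1.

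**Figure D2:**
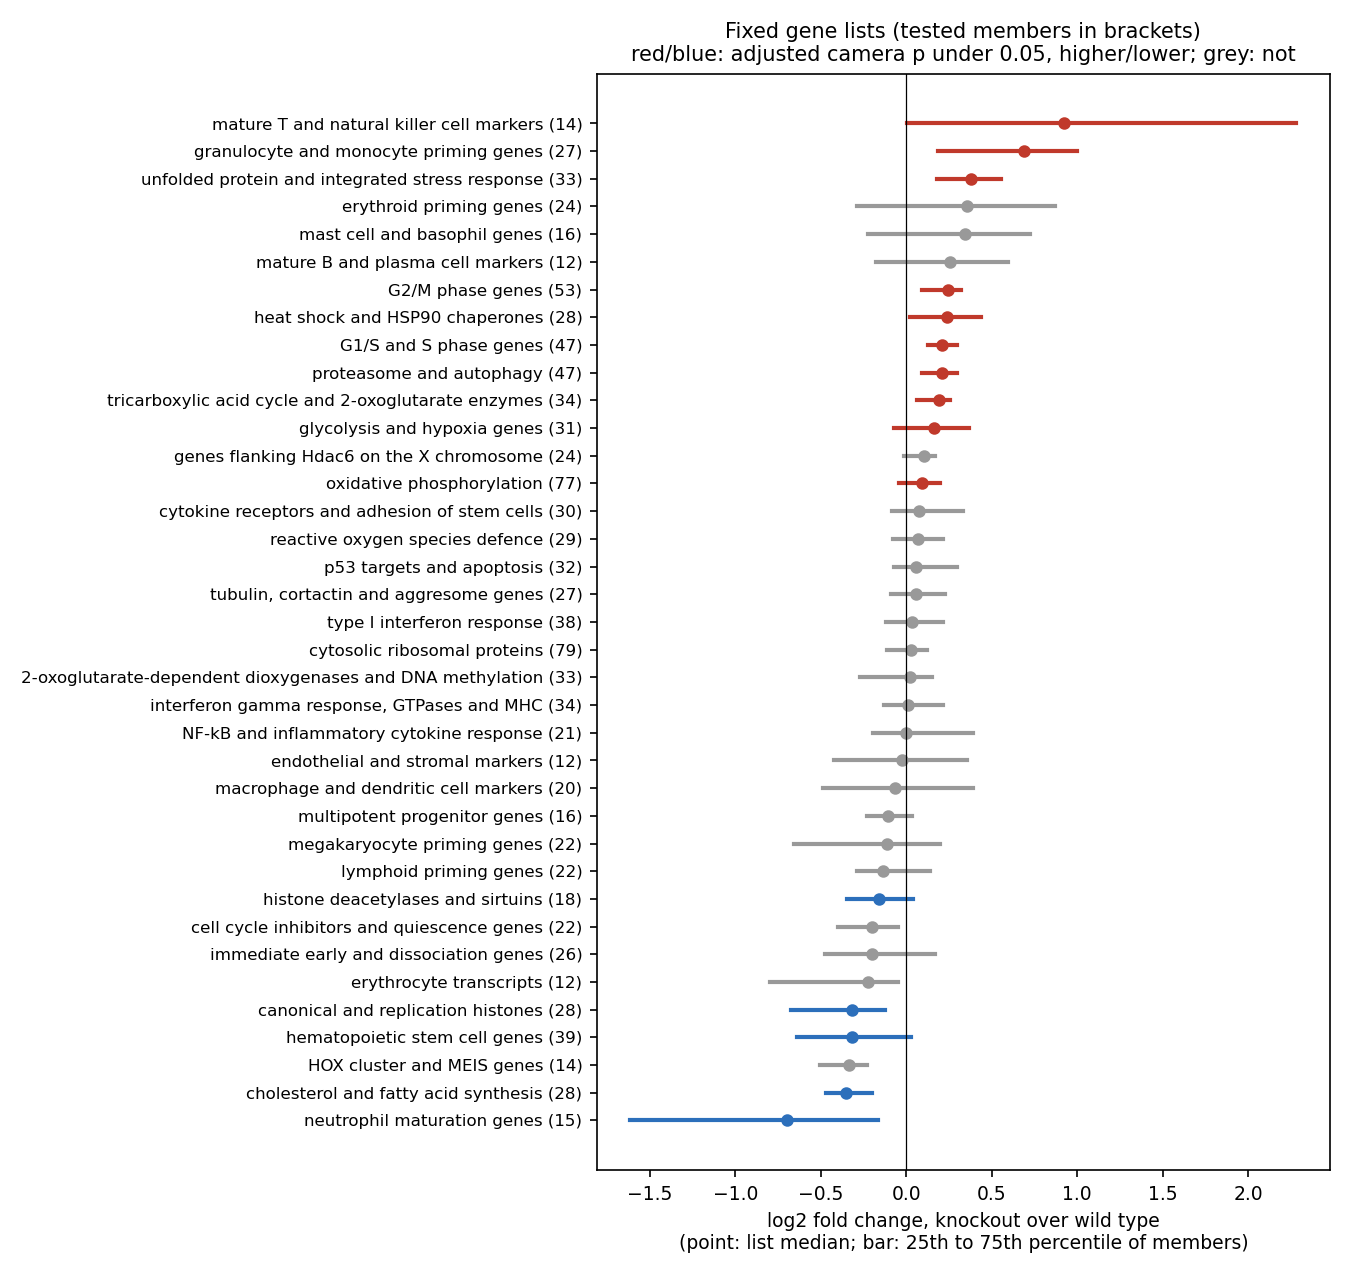
Log2 fold change of knockout over wild type (horizontal axis) for the 37 gene lists tested. Points are list medians, bars span the 25th to the 75th percentile of the tested members, whose number stands in brackets, and red and blue mark lists past an adjusted camera p of 0.05 on the higher and the lower side. Of the 15 marked lists 10 lie on the higher side, and 0 pass with an estimated correlation.

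Tricarboxylic acid cycle and 2-oxoglutarate enzymes, the list that holds Idh1, had a median log2 fold change of 0.19 with 29 of 34 above WT (camera adjusted p = 0.000992, and adjusted p = 0.602 with an estimated correlation). Dlst (0.34), Fh1 (0.31), Cs (0.27) and Dld (0.25) had the smallest p, and 0 members passed when adjusted over the list alone. Without knockout replicate 1 the median was 0.10. Glycolysis and hypoxia genes had a median of 0.16 (22 of 31 above WT, camera adjusted p = 0.0338, and adjusted p = 0.602 with an estimated correlation), with Ero1a (0.77), Pgam1 (0.49), Ldha (0.49) and Gapdh (0.44) leading. Oxidative phosphorylation genes had a median of 0.09 (53 of 77 above WT, camera adjusted p = 0.0332, and adjusted p = 0.822 with an estimated correlation), with Cyc1 (0.60), Uqcrfs1 (0.50), Cycs (0.50) and Cox5a (0.46) leading. In both lists 0 members passed when adjusted over the list alone. Knockout replicate 3 stood apart from the other knockout libraries in both: its oxidative phosphorylation mean of -0.15 lay below all WT libraries (-0.09 to 0.05), and its glycolysis mean of -0.11 lay within the WT range (-0.18 to 0.02). Without knockout replicate 1 the oxidative phosphorylation list ranked to the lower side by camera (adjusted p = 0.941), while its median of 0.02 stayed above 0. The list did not pass without WT replicate 2 (0.187, median 0.09), WT replicate 3 (0.2, median 0.06) or knockout replicate 2 (0.0702, median 0.07). It also did not pass with library size alone as scaling (0.149) or with the stricter filter (0.0706), and its median was 0.18 without knockout replicate 3. The glycolysis list did not pass without WT replicate 1 (0.127, median 0.10), WT replicate 3 (0.0648, median 0.20), knockout replicate 1 (0.142, median 0.05) or knockout replicate 2 (0.0745, median 0.12).

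Granulocyte and monocyte priming genes were higher as a group (median 0.69, 23 of 27 above WT), with a camera adjusted p of 3.49e-05, and adjusted p = 0.602 with an estimated correlation. Knockout replicate 2 stood apart: its level of Mpo, the myeloperoxidase gene, was 14157 CPM against 4277 to 6581 CPM in the other libraries, and without it the list median was 0.10 and the list did not pass (adjusted p = 0.106). Cst7 (0.83), Csf2rb (0.80) and Calr (0.55) were higher when adjusted over the list alone, and Ly86 had a log2 fold change of 1.41. Neutrophil maturation genes were lower (median -0.70, 12 of 15 below WT), with a camera adjusted p of 2.6e-05, and adjusted p = 0.602 with an estimated correlation. When adjusted over the list alone, 6 were lower, among them the granule genes Ltf, Ngp and Camp and the calprotectin gene S100a8. All were at low levels. Ltf measured 15.3 ± 9.43 CPM in WT and 2.16 ± 1.00 CPM in the knockout, and Ngp 17.8 ± 10.8 and 4.16 ± 1.94 CPM. S100a8 measured 15.4 ± 5.14 and 5.87 ± 2.51 CPM, and Camp 7.68 ± 4.27 and 2.14 ± 1.53 CPM. Among WT libraries Ltf ran from 5.87 to 24.7 CPM and Ngp from 10.1 to 30.1 CPM. Whether mature neutrophils left in the sort contributed to these levels was not tested.

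The list of mature T and natural killer cell markers was higher as a group (median 0.92, 10 of 14 above WT). Lineage depletion is meant to remove mature cells, but whether it covered natural killer cells was not checked here. The camera adjusted p was 0.0015, and adjusted p = 0.602 with an estimated correlation. The list mean was 1.01 and 0.88 in knockout replicates 2 and 3, while in knockout replicate 1, at -0.35, it lay within the WT range of -0.88 to -0.26. Il2rb, Cd7, Gzma, Ncr1, Prf1 and Ccl5 were higher and Lck lower when adjusted over the list alone. Il2rb, the interleukin-2 receptor beta chain, stood at 8.78, 23.6 and 33.3 CPM in knockout replicates 1, 2 and 3, against 2.87 to 5.76 CPM in WT. Cd7 measured 1.83 ± 1.23 CPM in WT and 12.3 ± 7.19 CPM in the knockout, Ncr1 1.58 ± 0.95 and 7.74 ± 6.25 CPM, and Gzma 0.38 ± 0.03 and 3.40 ± 3.68 CPM. The list did not pass without knockout replicate 3 (adjusted p = 0.085, median 0.84) or with the stricter filter on low counts (0.535).

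Histone deacetylases and sirtuins were lower as a group (median -0.16, 13 of 18 below WT, camera adjusted p = 0.00284, and adjusted p = 0.602 with an estimated correlation). This list holds Hdac6, the 1 member past the threshold over all genes and when adjusted over the list alone, and with Hdac6 taken out its adjusted p was 0.276. The median was -0.07 without knockout replicate 1. Hdac11 (-0.86), Hdac2 (0.63) and Sirt3 (-0.36) followed. Canonical and replication histone genes had a median of -0.32 (24 of 28 below WT, camera adjusted p = 0.0135, and adjusted p = 0.602 with an estimated correlation), with H2ac6 (-1.08), H2bc8 (-0.98), H2ac18 (-0.93) and H4c4 (-0.66) leading and 0 passing when adjusted over the list alone. Histone genes have near-identical copies, so single members are uncertain. The list mean of WT replicate 2, -0.14, lay below those of knockout replicates 1 (-0.07) and 2 (-0.13). The histone list did not pass without WT replicate 1 (0.107, median -0.34), WT replicate 3 (0.139, median -0.16) or knockout replicate 3 (0.171, median -0.21), or with the stricter filter on low counts (0.193).

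**Figure D3:**
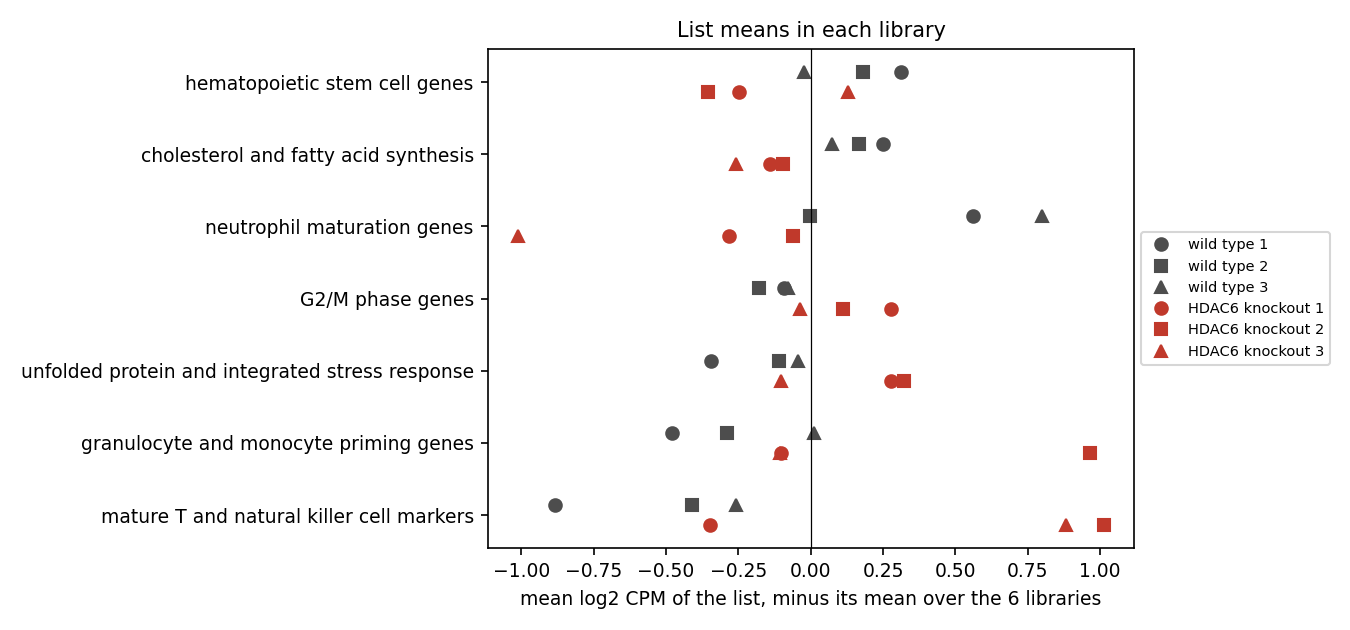
Mean log2 CPM of 7 gene lists in each library, minus the mean over the 6 libraries (horizontal axis); grey marks wild type, red the knockout, and the symbol the replicate number. For the cholesterol list the groups do not overlap, while for the stem cell list knockout replicate 3 (0.13) lies above WT replicate 3 (-0.02).

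The remaining lists did not pass. Among blood lineages the medians and adjusted p by camera were 0.36 and 0.067 for erythroid priming (Tfrc higher when adjusted over the list alone), 0.34 and 0.163 for mast cell and basophil genes (Fcer1a, Mcpt8 and Prss34 higher), -0.11 and 0.11 for megakaryocyte priming (Plek and Mmrn1 lower), -0.11 and 0.348 for multipotent progenitor genes, and -0.33 and 0.067 for HOX cluster and MEIS genes. Lymphoid priming genes had a median of -0.14 and a mean of 0.04 (0.277). On the higher side erythroid priming (3.89e-08) and mast cell genes (0.042) passed without knockout replicate 1, and erythroid priming also with the stricter filter (0.0393) and library size alone (0.0323). On the lower side HOX genes passed without WT replicate 2 (0.0342), without knockout replicate 1 (0.0482) and with the stricter filter (0.0395), lymphoid genes without WT replicate 3 (0.034) or knockout replicate 3 (0.0492), and megakaryocyte genes without knockout replicate 3 (0.0159). These medians also rested on single libraries, at 0.20 for erythroid priming without knockout replicate 3, 0.05 for mast cell genes and -0.04 for multipotent progenitor genes without knockout replicate 2, and -0.14 for HOX genes without WT replicate 1. The sign turned for megakaryocyte genes without knockout replicate 1 (0.03) and for lymphoid genes without WT replicate 1 (0.03) or knockout replicate 2 (0.05). Of other cell types, mature B and plasma cell markers had a median of 0.26, and 0.03 without WT replicate 3 or knockout replicate 3 (0.696 on all libraries; Xbp1 higher and Sdc1 lower when adjusted over the list alone), erythrocyte transcripts -0.22 (0.401), and 0.04 without knockout replicate 1, and macrophage and dendritic cell markers -0.07 (0.684). Endothelial and stromal markers had a median of -0.02 and a mean of 0.08 (0.832). Over left-out libraries the median ran from -0.21 (without knockout replicate 1) to 0.07 (without WT replicate 1) for macrophage and dendritic cell markers, and from -0.23 (without WT replicate 1) to 0.10 (without knockout replicate 1) for endothelial and stromal markers.

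Immediate early and dissociation genes had a median of -0.20 (adjusted p = 0.225), and -0.10 without knockout replicate 1, with Fos lower and Socs3 higher when adjusted over the list alone. Socs3, a feedback inhibitor of cytokine signalling, measured 6.92 ± 1.59 CPM in WT and 38.0 ± 26.2 CPM in the knockout, a log2 fold change of 2.46 (SE 0.47) that DESeq2 called. It was also the 1 member of the NF-kB and inflammatory list to pass when adjusted over the list alone (median -0.00, mean 0.18, adjusted p = 0.696). Type I interferon genes (median 0.04, 0.696) and interferon gamma, GTPase and MHC genes (0.01, 0.99) did not pass, yet both passed on the lower side without knockout replicate 3 (0.0117 and 0.00587, medians -0.25 and -0.19) and on the higher side without knockout replicate 1 (0.00111 and 0.000151, medians 0.18 and 0.20). Medians were 0.06 for p53 targets and apoptosis (0.612, and a median of 0.01 without knockout replicate 2) and 0.05 for tubulin, cortactin and aggresome genes (0.383, and a median of 0.15 without WT replicate 3). For reactive oxygen species defence the median was 0.07 (0.15, and 0.0236 without knockout replicate 3, median 0.13). For cytokine receptors and adhesion of stem cells it was 0.07 (0.684, and 0.042 without knockout replicate 1), and 0.0015 without knockout replicate 2. For 2-oxoglutarate-dependent dioxygenases and DNA methylation the median was 0.02 and the mean -0.03 (0.696), and for cytosolic ribosomal proteins 0.03 and -0.00 (0.99). Genes flanking Hdac6 on the X chromosome had a median of 0.10 (0.345), and 0.01 without knockout replicate 1. Of 24 tested members 17 lay above WT, and the directional test of fry gave an adjusted p of 0.0628, the lowest of the lists. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had log2 fold changes between -0.05 and 0.15, and the mitochondrial genome list had 0 members among the genes analysed.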

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

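The tests on FPKM, on DESeq2 with filtered genes or filtering set for 0.05, with the newer edgeR option, with library size alone, by fry for change in either direction and on the deacetylase list without Hdac6 were chosen after the result was seen. Hdac6 passed under every alternative run, with log2 fold changes from -2.80 to -2.34. The count of genes higher in the knockout was 0, and by DESeq2 120, on filtered genes 117 and with filtering set for 0.05 118; the count lower was 1, and by DESeq2 61, 59 and 61. The cause was not tested. In simulation 20.2% of DESeq2 calls were false, against 8.6% for edgeR. Those counts were drawn with the dispersions edgeR estimated and with genes varying independently, so the shares need not hold for the real counts. Leaving out each library gave 0 to 30 higher genes, 1 to 14 lower genes and 12 to 19 lists, against 15 lists on all libraries. With an estimated correlation 0 lists passed (lowest adjusted p 0.602). By the directional test of fry 0 lists passed as well. The lowest adjusted p of that test was 0.0628, for genes flanking Hdac6 on the X chromosome, on the higher side. The fry test for change in either direction compares no list with other genes. It passed for 3 lists, the deacetylase list with Hdac6 (0.00284) and the cholesterol and B cell lists (0.0385 each). The estimated correlation allows for genes that vary together, and reached 0.659 for oxidative phosphorylation.

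With the replicate number as a block, 0 genes were higher, 1 was lower and 17 lists passed, the added ones being erythroid priming and cell cycle inhibitors (0.0466 each). Same-numbered libraries did not deviate together (r of 0.033, -0.039 and -0.122). So few pairs cannot show whether the samples were paired, which the labels do not say.

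The direction of the fold change turned for Idh1 (-0.031 to 0.52 over left-out libraries), and that of the camera test for oxidative phosphorylation (adjusted p from 5.04e-06 to 0.941) and lists that had not passed. Over left-out libraries their adjusted p ran from 0.253 to 0.977 for ribosomal proteins, 0.577 to 0.953 for endothelial markers, 0.000151 to 0.937 for interferon gamma genes, 0.142 to 0.903 for B cell markers, 0.00111 to 0.95 for type I interferon genes, 0.042 to 0.937 for cytokine receptors, 0.183 to 0.926 for macrophage markers and 0.541 to 0.893 for dioxygenases. Ribosomal proteins also turned with RLE factors (0.94), no filter (0.886) and fry (0.968), interferon gamma genes with no filter (0.992) and the stricter filter (0.955), B cell markers (0.99) and NF-kB genes (0.927) with the stricter filter, and endothelial markers with library size alone (0.95). The cause was not tested.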

Other observations

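The tests of knockout replicate 2 alone, of contaminating cells, of chromosome 12 and of the correlations of the stem cell list with lists other than G2/M and cholesterol were not set before the result was seen; the other tests were. The lower cholesterol genes were weighed against 2 technical or cellular explanations. Gene length and GC content are argued against as the whole cause, since the list median was -0.35 before and -0.31 after their trend was removed, with a camera adjusted p of 1.84e-06. A shift of cell states shared with the stem cell genes stays open: over the deviations of 6 libraries from their group means the list means had a Pearson r of -0.178 (permutation p = 0.722, adjusted 0.722 over 6 relations; Spearman rho -0.257, permutation p = 0.722), and 0.048 without the 2 libraries farthest from the median. An effect of HDAC6 loss may explain the pattern as a hypothesis, but these libraries cannot separate it from such a shift.

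Lower stem cell genes with higher cell cycle, chaperone and myeloid genes could come from the knockout or from a different mix of cells in the sorted gate. The trend on length and GC content is argued against, since after its removal the medians were 0.22 for G2/M and -0.331 for stem cell genes, and so is knockout replicate 2 alone for the stem cell, G1/S, G2/M, unfolded protein and heat shock lists, since without it the smallest of these 5 medians was 0.162 in size; for the granulocyte and monocyte list that library stays open, since without it the median was 0.104, against 0.69, and the camera adjusted p was 0.106. A different share of committed progenitors cannot be told apart from genotype: within groups the stem cell and G2/M means had a Pearson r of -0.606 (permutation p = 0.389, adjusted 0.467; Spearman rho -0.486, permutation p = 0.583), and -0.241 without the 2 farthest libraries, so the relation rests on those. Of the other 4 relations, r was -0.85 for G1/S (permutation p = 0.111, adjusted 0.222; rho -0.714, permutation p = 0.222), -0.883 for heat shock (0.083, 0.222; -0.771, 0.194), -0.728 for granulocyte and monocyte genes (0.194, 0.291; -0.829, 0.139) and -0.966 for the unfolded protein list (0.028, the smallest that 36 pairings can give, 0.168; -1, 0.028). Without the same 2 libraries these were -0.446, -0.023, -0.671 and -0.957, so those for G1/S and heat shock rest on the 2 libraries as well. After adjustment 0 of the 6 relations passed, but this count decides nothing. Even the smallest permutation p that 36 pairings can give, 0.028, had an adjusted p of 0.168.

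The higher list of T and natural killer cell markers was weighed against contaminating cells and a passenger region on chromosome 6. Of the list's tested members, 4 lie on that chromosome. The region is argued against as the whole cause, since the 10 tested members on other chromosomes had a median log2 fold change of 1.663. Of 37 genes at p under 0.001, 2 lay on chromosome 6 (two-sided Fisher's exact p = 0.708). A share over the whole chromosome cannot show a local cluster. A part of the region in the change of the 4 tested members on it was therefore not tested. Contaminating mature cells stay open: the largest excess of Cd3e, Cd3d, Cd3g, Gzma, Ccl5 or Prf1 over WT was 0.388 of that of Il2rb in the same library, the share that such cells would bring was not measured, and Gzma and Ccl5 exceeded the WT mean by 7.09 and 6.57 CPM in knockout replicate 2 and by 2.05 and 5.05 CPM in replicate 3, and differed from it by -0.08 and 0.42 CPM in replicate 1. Prf1 exceeded the WT mean by 1.62, 4.28 and 0.84 CPM in knockout replicates 1, 2 and 3, and the share of 0.388 was that of Prf1 in replicate 1. Cd3e, Cd3d and Cd3g exceeded the WT mean by at most 0.47 CPM.

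A scan of 20 chromosomes at 5 p limits, made after the results were seen, found 7 of 452 tested genes of chromosome 12 at p under 0.001 (Sdc1, Syne2, Fut8, Fos, Gm40892, Btbd7 and Serpina3g), against 37 of 12789 in all (Fisher's exact p = 0.00027, adjusted 0.0054 over the chromosomes at that limit). The adjusted p was 0.0187 at a limit of 0.002, 0.41 at 0.005, 0.787 at 0.01 and 0.746 at 0.05, and the 7 genes had log2 fold changes of both signs. Of 10000 random sets of the chromosome's genes, a share of 0.2296 lay as close in gene order, and 0 of the 7 genes shared a symbol family.

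The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes higher by edgeR the real split gave 0, so that all 10 splits gave as many by construction and this count decides nothing; the highest other, 1, counts calls in either direction. For genes lower the real split gave 1 and the highest other 1 (3 splits). Camera called 15 lists in the real split and up to 19 in another (3 splits gave as many), and DESeq2 called 181 genes and up to 252 (2 splits). The split with 252 set WT replicates 1 and 2 with knockout replicate 3 against WT replicate 3 with knockout replicates 1 and 2, and shared 12 genes with the real calls. In that split edgeR called 1 gene. A grouping that mixes the genotypes can thus give as many DESeq2 calls, and the cause was not tested. The first principal component (33% of variance) placed the 3 WT libraries (-48.57, -24.59 and -3.23 for replicates 1 to 3) below the 3 knockout libraries (26.7, 46.56 and 3.12), with the replicate 3 libraries closest to each other, and Hdac6 was low in all 3 knockout libraries.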
